A study of Mus musculus with 16 samples.

How the data were processed

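Brain RNA of neonatal mice was compared on 16 cDNA arrays with 2 colours, 4 each for wild type, Cx43 null, Cx43 heterozygous and Cx32 null mice. Per the labels, brain cDNA carried Cy3 and was hybridised beside a Cy5 reference made at once for all arrays from a pool of adult tissues that included brain, heart, kidney, liver and lung. The labels of wild-type replicates 3 and 4 state the dye of the reference only. For wild-type replicate 3 the title and the channel label carry different replicate numbers, and the title was followed. The titles of the Cx32 null samples do not say neonatal, but their descriptions do. The labels do not say whether a sample is 1 animal or a pool, so p-values measure the spread between these samples.

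The deposited values are log ratios, 1 per spot and array, and were read as log2. The authors' labels state neither the log base, nor the numerator, nor the normalization within an array. The range of the values excludes log10 but not the natural logarithm, which would make every fold change larger and leave directions and p-values as they are. Brain over reference was taken as the likely direction, because the median of the neuron list lay above that of the reference tissue list on 16 of 16 arrays. Empty cells are spots without a value, for a reason the labels do not state. No intensities, backgrounds or spot flags were deposited, so the signal over background of a spot is not known.

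The table held 28704 spots. A single gene symbol could be given to 18511 of them, 18267 through the gene identifier and 244 as the platform gives it. Another 937 spots list several symbols and 9256 have no entry. Each array was centred on its median, which had lain between -0.13 and 0.28 on the log2 scale. A spot was kept if each group had at least 3 of 4 values, which left 19951 spots. Spots of 1 gene were averaged. This gave 14292 transcripts for testing, of which 8654 are named genes and 5638 are spots without a single symbol, each counted on its own. Between 21010 and 24819 spots had a value on an array, and with 4 arrays per group the number of arrays limits the precision. No spot is named Gjb1.

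The 4 group means were fitted to all 16 arrays with limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3, and the 6 contrasts between groups were tested. A transcript passed at a Benjamini-Hochberg adjusted p under 0.05, adjusted over all transcripts of a contrast. Gene lists were tested with limma's camera at its preset correlation between genes of 0.01, adjusted over the 27 lists with at least 5 measured members; missing values were replaced by the group mean for that test alone. Lists were also tested with the correlation estimated from the data. Counts of list members were made over all transcripts and adjusted over the list alone.

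The 29 lists cover cell types (neurons, astrocytes and radial glia, oligodendrocytes and myelin, microglia, endothelium, meninges, choroid plexus, red blood cells), neighbouring or reference tissues (skeletal muscle, skin, reference tissues), neuronal signalling (synaptic vesicles, glutamate, GABA, ion channels, calcium and purines), junctions (connexins and pannexins, adherens and tight junctions), the cytoskeleton (actin, tubulins), metabolism (glycolysis, respiratory chain, cholesterol), protein turnover (ribosomal proteins, chaperones, proteasome), and cell cycle, apoptosis and Wnt and Notch signalling. The connexin list had 3 measured members and the oligodendrocyte list 4, so neither was tested as a list.

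Lists, tests, groups and the rule for named genes were chosen before the data were examined. For each line against wild type the rule takes Gja1 and Gjb1, then, among named genes that pass and whose values do not overlap between the groups, the 10 with the largest rise and the 10 with the largest fall (5 and 5 between lines). For each list it takes up to 2 passing members in each direction. Where fewer genes are given, fewer met the rule, except that 1 gene that met it in Cx43 null brain is left out of the text. For the 2 lists too small to test, every measured member is given, outside this rule.

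Shared calls between lines were counted in the same direction and set beside the number expected for unrelated calls, beside 100 simulations of unchanged groups with shared controls, and beside fits in which each line was given 2 of the wild-type arrays, in 6 ways. The spread of a group is the median over transcripts of the SD between its 4 arrays, with a jackknife error. The fit was tested on simulated data: among 14292 transcripts, 98 to 99 of 100 changes of 2 log2 units were recovered and 53 to 61 of 100 changes of 1 log2 unit, and 4.91% to 6.17% of the calls were false. The simulated transcripts were independent and had the same spread in every group. The real median SD was 0.38 in wild type and 0.20 in Cx43 heterozygous brain, so these rates need not hold for the real arrays.

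Alternatives covered the scaling (values as deposited, quantile, cyclic loess), the filter on missing values, the fit (the 2 groups alone, the replicate number as a block, array weights, trend and robust options), spots tested singly, a fold of at least 1.5 with an unadjusted p, wild-type replicates 2 and 3 as 1 sample, and each array left out in turn. Alternatives added after the data were seen left out blocks of spots that were out of step between arrays, or wild-type replicate 1 and Cx43 null replicate 1 together. A block is a run of spot numbers in a layout of 48 blocks of 23 by 26 spots, which was inferred from the spot numbers and values because the labels give no layout. Block correlations and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No deposited array was left out of the reported values.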

Results

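Brains of neonatal mice were profiled in 4 groups of 4 samples: wild type, Cx43 null, Cx43 heterozygous and Cx32 null. Connexin 43, encoded by Gja1, is the main gap junction protein of astrocytes. Connexin 32, encoded by Gjb1, is a gap junction protein of oligodendrocytes and Schwann cells. Each sample was hybridised on 1 array beside a common reference of pooled adult tissues, and every value below is a log2 ratio of brain to that reference, or a difference between groups of such ratios. The number of spots with a value ran from 22001 to 24747 on the wild-type arrays, from 23218 to 24819 for Cx43 null, from 21293 to 23075 for Cx43 heterozygous and from 21010 to 23144 for Cx32 null. The log base and the numerator are not stated by the labels, so folds hold if the values are log2 and rises and falls hold if brain is the numerator. Errors of log2 changes are standard errors from limma, whose fit gives all 4 groups 1 common spread per transcript. They need not match the spread of the 2 groups compared. The n is 4 arrays per group, or 3 where a gene has no value on 1 array, which is given for the genes with the largest changes.

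Gja1 fell in all 3 lines. It fell 10.5-fold in Cx43 null brain (log2 change -3.40 ± 0.37 SE, adjusted p = 0.000347), 7.61-fold in Cx43 heterozygous brain (-2.93 ± 0.37, adjusted p = 0.000116) and 2.74-fold in Cx32 null brain (-1.46 ± 0.37, adjusted p = 0.00976). The group means of its log2 ratio were 1.56 ± 0.63 (SD, n = 4) in wild type, 0.11 ± 0.14 in Cx32 null, -1.36 ± 0.34 in Cx43 heterozygous and -1.83 ± 0.96 in Cx43 null brain, and every array of the lines lay below every wild-type array. Between Cx43 null and Cx43 heterozygous brain the difference was -0.47 (95% interval -1.25 to 0.32, adjusted p = 0.631), -0.88 without Cx43 null replicate 1 and -0.11 without replicate 4. Cx43 null and Cx32 null brain differed by -1.94 (adjusted p = 0.0536), and Cx43 heterozygous and Cx32 null brain by -1.47 (adjusted p = 0.061). These 2 differences passed in 9 and 5 of 20 alternatives. For Cx43 null the adjusted p ranged from 0.00101 to 0.184 and was 0.0433 with values as deposited, 0.0141 under quantile scaling and 0.0117 without Cx43 null replicate 1. For Cx43 heterozygous it ranged from 0.00162 to 0.175 and was 0.025 under quantile scaling. Gja1 was read by 1 spot, whose position relative to the deleted part of the gene is not known. With the wild-type and Cx43 null arrays fitted alone, the change in Cx43 null brain kept its size but had an adjusted p of 0.0747, in a range of 5.17e-06 to 0.0747 over the alternatives. Gja1 also fell in Cx32 null brain, whose label names the loss of another gene. The folds against wild type therefore need not be the effect of the Gja1 alleles alone. Against Cx32 null brain, Gja1 was 3.84-fold lower in Cx43 null and 2.78-fold lower in Cx43 heterozygous brain, and neither difference passed, as given above. Gjb1 could not be followed, since no spot carries its name.

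**Figure D1:**
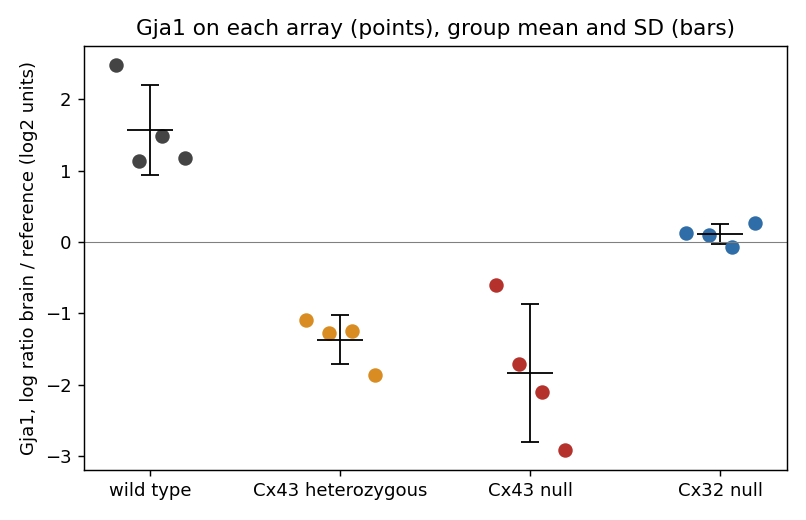
Log2 ratio of Gja1 (brain over reference) on each of the 16 arrays, with the mean and SD of each group of 4. The wild-type mean is 1.56 and the Cx43 null mean -1.83, and no array of the lines reaches the wild-type arrays.

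The comparison of Cx43 null with wild-type brain asks which transcripts follow the loss of connexin 43. Proteasome and chaperone genes were lower in Cx43 null brain: 9 of 35 measured proteasome genes fell and 0 rose (16 and 0 adjusted over the list alone), and 9 of 40 chaperone genes fell and 0 rose (15 and 0). Both lists were lost with an estimated correlation between genes (adjusted p = 0.818), and 26 and 31 of their genes did not pass. The median log2 change was -0.59 for the proteasome list (camera, adjusted p = 7.49e-08) and -0.53 for the chaperone list (adjusted p = 6.75e-06), and without wild-type replicate 1 it was -0.35 and -0.30. Igfbp4, a binding protein of insulin-like growth factors, fell 4.06-fold (-2.02 ± 0.33, adjusted p = 0.0051), and Ptgds, the prostaglandin D synthase of the leptomeninges and choroid plexus, fell 4.44-fold (-2.15 ± 0.41, adjusted p = 0.0102). Ntn1, which encodes the axon guidance protein netrin 1, rose 2.78-fold (1.47 ± 0.34, adjusted p = 0.0177). Of 14292 transcripts, 1556 passed, 627 higher and 929 lower, and 933 of these are named genes.

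Among the proteasome members, Psmb6 fell by 1.40 ± 0.40 and Psmd13 by 1.40 ± 0.26. Stip1, a co-chaperone of Hsp70 and Hsp90, fell by 1.31 ± 0.31, and Hspa9, the mitochondrial Hsp70, by 1.14 ± 0.28. With an estimated correlation between genes none of the 27 lists passed, and the 2 that follow had an adjusted p = 0.818 as well. In the respiratory chain and ATP synthase list 7 of 51 genes fell and 0 rose (8 and 0 adjusted over the list alone; median -0.37, adjusted p = 0.000126), with the complex I subunits Ndufv1 at -1.87 ± 0.34 and Ndufa10 at -1.63 ± 0.46. In the actin list 9 of 38 genes fell and 0 rose (12 and 1 adjusted over the list alone; median -0.30, adjusted p = 0.0027), among them Actr3, a subunit of the Arp2/3 complex, at -2.17 ± 0.42 (n = 3 wild-type arrays) and the severing protein gelsolin, Gsn, at -1.56 ± 0.33. Wild-type replicate 1 stood above the other wild-type arrays in these lists: the proteasome median was 1.47 on it and 0.50 to 0.60 on the others, and the respiratory chain median was 0.62 on it and -0.94 to -0.64 on the others. Without it the respiratory chain list (adjusted p = 0.208, lowest 1.59e-07 over its alternatives) and the actin list (adjusted p = 0.0645, lowest 0.000589) no longer passed, while the proteasome list (1.05e-05) and the chaperone list (0.000488) did. The actin list was also lost under quantile scaling (adjusted p = 0.0599). The respiratory chain median was -0.03 without wild-type replicate 1 and -0.55 without replicate 3.

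Other large falls in Cx43 null brain were Hpx, the haem-binding plasma protein hemopexin (-2.59 ± 0.75), the epidermal keratin Krt10 (-2.26 ± 0.44, n = 3 null arrays) and the cytochrome P450 Cyp2d9 (-1.99 ± 0.45). Hpx and Cyp2d9 had low mean log2 ratios in both groups (-6.12 and -4.15 in Cx43 null, -3.53 and -2.16 in wild type). Ccdc184 rose by 1.47 ± 0.29 and Fam161b by 1.24 ± 0.27. Another 9 genes named by the rule lie wholly or in part in blocks of spots where at least 1 array was out of step with the others. They are Gmppb (2.75 ± 0.58, n = 3 wild-type arrays), Ankrd50 (1.59 ± 0.29, n = 3 in each group), the kinesin Kif1a (2.82-fold higher) and Stard10 (-2.15 ± 0.42) in a block where wild-type replicate 4 did not follow the other arrays, and Tfpt (2.10 ± 0.36), Cnnm4 (1.68 ± 0.32), Lrrc40 (-2.07 ± 0.53, n = 3 null arrays) and Gstp1 (-1.91 ± 0.42) in a block where 7 arrays, all 4 wild-type arrays among them, were displaced against the other 9. Tfpt, Cnnm4, Lrrc40 and Gstp1 were thus read mostly from other spots in Cx43 null than in wild-type brain. Wsb1 (1.24 ± 0.25) has 4 spots, of which some lie in blocks out of step. Psmd13 and Hspa9 lie in such blocks as well. The change of Gmppb was 3.86 and that of Hpx -1.94 without wild-type replicate 1.

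The count of 1556 depended on single arrays. It was 107 without Cx43 null replicate 3, 492 and 515 without wild-type or Cx43 null replicate 2, 609 without Cx43 null replicate 4, 823 without wild-type replicate 1, 2530 without Cx43 null replicate 1 and 3052 without wild-type replicate 4. With the 8 arrays of these groups fitted alone by limma, 0 transcripts passed and 3111 had an unadjusted p under 0.05. Of the 19 genes that the rule named by size, 8 passed in every fit with 1 array left out. Without Cx43 null replicate 3 the adjusted p was 0.0684 for Fam161b, 0.0548 for Wsb1, 0.0665 for Krt10, 0.0516 for Cyp2d9 and 0.0752 for Gstp1. Gmppb, Kif1a, Ntn1, Hpx and Lrrc40 were lost without any 1 of several arrays, with highest adjusted p values of 0.0558, 0.144, 0.0785, 0.119 and 0.137.

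Cx43 heterozygous brain was compared with wild type to ask which transcripts follow a reduced gene dose. Chaperone genes were lower: 23 of 40 fell and 0 rose (30 and 0 adjusted over the list alone; median -0.71, adjusted p = 1.74e-06). This list and the proteasome list below were lost with an estimated correlation between genes (adjusted p = 0.828 for each). Hspa8, the constitutive Hsp70, fell 3.38-fold (-1.76 ± 0.33) and the protein disulfide isomerase Pdia6 3.69-fold (-1.88 ± 0.42). Of 35 proteasome genes 19 fell and 0 rose (20 and 0 adjusted over the list alone; median -0.67, adjusted p = 3.53e-06), with Psmd4 at -1.60 ± 0.25 and Psmd13 at -1.58 ± 0.26. The proteasome median was -0.37 without wild-type replicate 1. Ntn1 rose 4.11-fold (2.04 ± 0.34, adjusted p = 0.000544) and Panx1, which encodes the membrane channel pannexin 1, rose 3.49-fold (1.80 ± 0.33, adjusted p = 0.00114). Of 14292 transcripts 4481 passed, 1962 higher and 2519 lower, with 2754 named genes among them.

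With an estimated correlation between genes none of the lists that follow passed (adjusted p = 0.845 for the ribosomal list and 0.828 for the others). In the actin list 14 of 38 genes fell and 1 rose (15 and 1 adjusted over the list alone; median -0.45, adjusted p = 0.000401): Actr3 was at -2.74 ± 0.42, the tropomyosin Tpm1 at -1.94 ± 0.36 and the non-muscle myosin Myh9 at 0.60 ± 0.19. Of 21 glycolysis genes 9 fell and 0 rose (9 and 0 adjusted over the list alone; median -0.67, adjusted p = 0.00484), among them Pdk2, which inhibits pyruvate dehydrogenase (-1.65 ± 0.39), and the lactate dehydrogenase Ldhb (-1.60 ± 0.32). In the respiratory chain list 15 of 51 fell and 1 rose (15 and 1 adjusted over the list alone; median -0.46, adjusted p = 0.00341), with Ndufv1 at -2.25 ± 0.34, Ndufs8 at -1.77 ± 0.33 and Cox6c at 1.44 ± 0.49. Cytosolic ribosomal protein genes fell in 13 of 57 cases and rose in 2 (13 and 2 adjusted over the list alone; median -0.34, adjusted p = 0.0143), with Rps14 at -1.90 ± 0.42, Rpl15 at -1.63 ± 0.33 and Rpl9 at 0.65 ± 0.22. Without wild-type replicate 1 the respiratory chain list (adjusted p = 0.262, lowest 7.65e-05 over its alternatives) and the ribosomal list (0.516, lowest 0.000189) no longer passed, and without Cx43 heterozygous replicate 1 the ribosomal list did not (0.078). The respiratory chain median was -0.11 without wild-type replicate 1, and the ribosomal median was -0.04 without wild-type replicate 1 and -0.52 without replicate 3. Psmd13 and Rpl15 lie in blocks of spots out of step on some arrays.

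In Cx43 heterozygous brain the paraoxonase Pon1 fell 10.6-fold (-3.41 ± 0.55, n = 3 and 4), Hpx 10.2-fold (-3.35 ± 0.75), the retinol dehydrogenase Rdh7 to a similar degree (-3.17 ± 0.42, n = 3 and 4), plasminogen, Plg, 8.49-fold (-3.09 ± 0.40) and Cyp2d9 8.49-fold (-3.09 ± 0.45). Each was read by 1 spot, and brain lay far below the reference in both groups. Mean log2 ratios in heterozygous and wild-type brain were -6.98 and -3.57 for Pon1, -6.88 and -3.53 for Hpx and -6.2 and -3.04 for Rdh7. They were -4.81 and -1.73 for Plg and -5.24 and -2.16 for Cyp2d9. Gcdh, the glutaryl-CoA dehydrogenase, fell 9.50-fold (-3.25 ± 0.46), the nuclear RNA Neat1, which builds paraspeckles, 8.11-fold (-3.02 ± 0.56, n = 3 in each group) and Gm12966 7.74-fold (-2.95 ± 0.19, adjusted p = 3.32e-07). Genes that rose, outside the blocks out of step, included Ubl4b (2.41 ± 0.44), Nexmif (2.35 ± 0.29, n = 3 heterozygous arrays), C030034L19Rik (2.15 ± 0.57), the unconventional myosin Myo16 (2.11 ± 0.30), Rnf24 (2.09 ± 0.49) and Mier2 (2.00 ± 0.41). Gmppb (2.88 ± 0.58, n = 3 wild-type arrays), Kif1a (2.53 ± 0.43), Tfpt (2.51 ± 0.39, n = 3 heterozygous arrays) and Stard10 (-2.77 ± 0.42) lie in such blocks. Tfpt was read mostly from other spots in heterozygous than in wild-type brain. The change of Hpx was -2.70 and that of Gmppb 4.00 without wild-type replicate 1. All 19 genes that the rule named by size passed in every fit with 1 array left out, and the count stayed between 3244 and 5143. With the values as deposited, the median of all transcripts shifted by 0.17 and the share of passing transcripts that were higher went from 43.8% to 62.8%. It was 51.9% under cyclic loess and 47.9% under quantile scaling.

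Cx32 null brain was compared with wild type to ask which transcripts follow the loss of connexin 32, a protein of another cell type than connexin 43. Of 40 chaperone genes 20 fell and 0 rose (25 and 0 adjusted over the list alone; median -0.69, adjusted p = 4.55e-06), with Pdia6 at -2.28 ± 0.42 and Hspa8 at -1.66 ± 0.33. This list and the proteasome list below were lost with an estimated correlation between genes (adjusted p = 0.836 for each). Of 35 proteasome genes 14 fell and 1 rose (16 and 1 adjusted over the list alone; median -0.60, adjusted p = 6.27e-05). Without wild-type replicate 1 the medians were -0.45 for the chaperone and -0.32 for the proteasome list. Psmb3 fell 4.62-fold (-2.21 ± 0.36), and Psmb9, a subunit of the immunoproteasome, rose by 1.15 ± 0.35. Smarcc2, a subunit of the BAF chromatin remodelling complexes, rose 5.91-fold (2.56 ± 0.51, adjusted p = 0.00259), and Capg, which caps actin filaments, fell 6.91-fold (-2.79 ± 0.38, n = 3 and 4, adjusted p = 0.000389). Of 14292 transcripts 3962 passed, 1895 higher and 2067 lower, with 2414 named genes among them. The share that was higher, 47.8%, was 57.2% with values as deposited, 53.4% under quantile scaling and 51.6% under cyclic loess.

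The lists that follow were each lost with an estimated correlation between genes (adjusted p = 0.836 for each). Glycolysis genes fell in 9 of 21 cases and 0 rose (9 and 0 adjusted over the list alone; median -0.84, adjusted p = 0.00345), with Pdk2 at -1.59 ± 0.39 and the phosphoglycerate kinase Pgk1 at -1.63 ± 0.32. In the actin list 12 of 38 fell and 0 rose (13 and 0 adjusted over the list alone; median -0.27, adjusted p = 0.00354), with Actr3 at -2.62 ± 0.42 (n = 3 wild-type arrays) and Gsn at -2.07 ± 0.33. The respiratory chain list had 15 of 51 genes lower and 0 higher (15 and 0 adjusted over the list alone; median -0.41, adjusted p = 0.00905), with Ndufv1 at -1.95 ± 0.34 and Ndufa10 at -1.62 ± 0.42. Of 14 skeletal muscle genes 5 fell and 0 rose (6 and 0 adjusted over the list alone; median -0.59, adjusted p = 0.0112), with the tropomyosin Tpm2 at -1.94 ± 0.43 and the actinin Actn2 at -1.64 ± 0.34. Of 57 ribosomal protein genes 13 fell and 0 rose (13 and 0 adjusted over the list alone; median -0.25, adjusted p = 0.0206), with Rps14 at -1.63 ± 0.42 and Rpl8 at -1.46 ± 0.27. Without wild-type replicate 1 the respiratory chain list (adjusted p = 0.51, lowest 0.000325 over its alternatives) and the ribosomal list (0.682, lowest 0.000328) no longer passed, and the median of the ribosomal list turned to 0.10. It was -0.41 without wild-type replicate 2, -0.46 without replicate 3 and -0.15 without Cx32 null replicate 4. Without wild-type replicate 1 the respiratory chain median was -0.04 and the glycolysis median -0.42. Without Cx32 null replicate 4 the respiratory chain and ribosomal lists had adjusted p values of 0.0661 and 0.158, and under cyclic loess the muscle list was at 0.0627 (lowest 0.00691). Pgk1 and Rpl8 lie in blocks of spots out of step on some arrays.

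Other genes that rose in Cx32 null brain were C030034L19Rik (2.87 ± 0.57), the alpha-tubulin Tuba8 (2.44 ± 0.71), Ccdc184 (2.20 ± 0.29), Nckap5l (2.11 ± 0.49, n = 3 null arrays), the beta-adducin Add2, a protein of the membrane skeleton (2.05 ± 0.34), Nexmif (1.98 ± 0.29, n = 3 null arrays) and Hddc3 (1.86 ± 0.21). The falls included Cyp2d9 (-2.99 ± 0.45), Gcdh (-2.90 ± 0.46), Neat1 (-2.87 ± 0.53, n = 4 and 3), the transcriptional repressor Erf (-2.73 ± 0.49, n = 4 and 3), the LIM domain protein Fhl2 (-2.68 ± 0.38), Gm12966 (-2.63 ± 0.19, adjusted p = 2.07e-06), the glutathione transferase Gstm6 (-2.57 ± 0.41) and Tbata (-2.54 ± 0.36, n = 3 and 4). Cyp2d9 had a low mean log2 ratio in both groups (-5.1 in Cx32 null, -2.16 in wild type). Kif1a (2.87 ± 0.43) and Tfpt (2.56 ± 0.39, n = 3 null arrays) lie in blocks out of step. Tfpt was read mostly from other spots in Cx32 null than in wild-type brain. Of the 20 genes that the rule named by size, 19 passed in every fit with 1 array left out, and Tuba8 did not without wild-type replicate 4 (1.81, adjusted p = 0.051). The change of Erf was -2.09 without wild-type replicate 3 and -3.43 without replicate 4. The count stayed between 2838 and 4633 with 1 array left out, and was 2323 with the 8 arrays of these groups fitted alone.

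**Figure D2:**
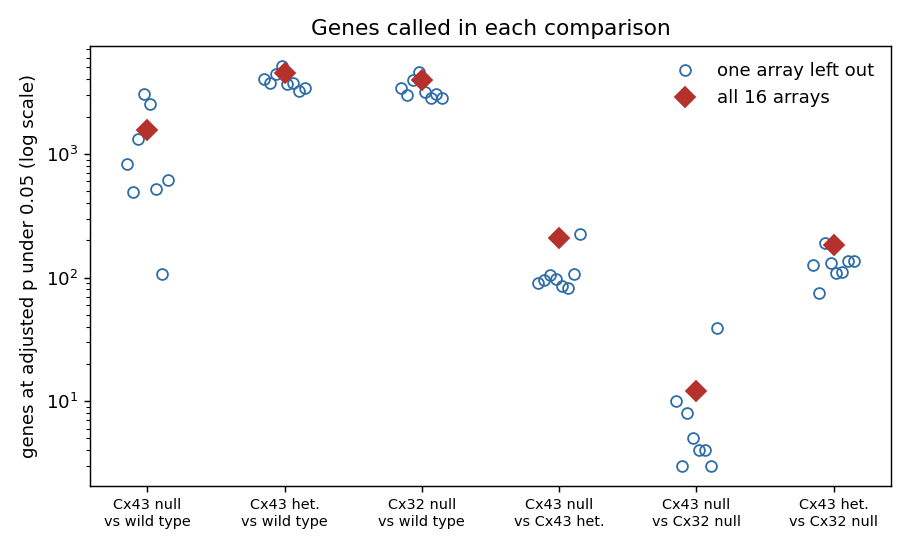
Number of transcripts that passed at an adjusted p under 0.05 in each of the 6 comparisons, on a log axis. Diamonds give the counts with all arrays, and open circles the counts with each array left out in turn. With all arrays, the counts against wild type are 1556, 4481 and 3962, and the counts between the lines are 208, 12 and 183.

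No list of cell type markers passed in the 3 lines, apart from skeletal muscle in Cx32 null brain. The astrocyte median was lower on all 12 arrays of the lines (-0.64 to 0.15) than on the 4 wild-type arrays (0.20 to 1.02), and so was the meningeal median (-0.81 to -0.43, wild type -0.29 to -0.03). Counts are given for Cx43 null, Cx43 heterozygous and Cx32 null brain in that order. Of 17 astrocyte and radial glia genes 3, 6 and 5 fell and 0, 2 and 0 rose (list adjusted p = 0.245, 0.32 and 0.136). Adjusted over the list alone, 4, 7 and 6 fell and 2, 3 and 0 rose. Sparcl1, an astrocyte matrix protein that promotes synapse formation, fell in Cx43 null (-1.18 ± 0.28) and Cx43 heterozygous brain (-1.68 ± 0.28). Ndrg2 fell in Cx43 heterozygous (-1.99 ± 0.31) and Cx32 null brain (-1.90 ± 0.31). Fabp7, a fatty acid binding protein of radial glia, rose by 0.81 ± 0.25 in Cx43 heterozygous brain. Of 17 microglia and macrophage genes 4, 7 and 6 fell and 1, 4 and 2 rose (list adjusted p = 0.245, 0.395 and 0.199). With p adjusted over the list alone, 6, 7 and 7 fell and 3, 4 and 2 rose. Ctss, the cathepsin of microglia, rose by 1.77 ± 0.47 and the integrin Itgam by 1.41 ± 0.27 in Cx43 heterozygous brain, while the class II gene H2-Aa fell by 1.44 ± 0.25. Among 23 neuron genes 0, 4 and 4 fell and 1, 4 and 2 rose (list adjusted p = 0.888, 0.817 and 0.976). The numbers were 0, 4 and 4 lower and 0, 4 and 3 higher adjusted over the list alone. Syn1, which encodes the synaptic vesicle protein synapsin I, fell in Cx43 heterozygous (-1.93 ± 0.27) and Cx32 null brain (-0.95 ± 0.27). Dpysl2, which acts in axon growth, rose by 0.96 ± 0.29 in Cx43 heterozygous brain.

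Vascular, meningeal and ventricular markers had 11, 16 and 9 measured genes. Of the endothelial genes 1, 2 and 1 fell and 1, 2 and 0 rose (list adjusted p = 0.954, 0.491 and 0.781). Counts were alike when adjusted over the list alone. Sparc fell in all 3 lines (-1.10 ± 0.22, -1.04 ± 0.22 and -1.15 ± 0.22). Of the meningeal genes 3, 6 and 6 fell and 0, 2 and 2 rose (list adjusted p = 0.245, 0.46 and 0.284). When adjusted over the list alone, 3, 6 and 6 fell and 0, 3 and 2 rose. Igfbp4 fell in Cx43 heterozygous (-2.57 ± 0.33) and Cx32 null brain (-2.37 ± 0.33), as did the proteoglycan gene Dcn (-2.21 ± 0.41 and -1.79 ± 0.41). Of the choroid plexus genes 3, 3 and 3 fell and 0, 2 and 1 rose (list adjusted p = 0.842, 0.62 and 0.781). Adjusted over the list alone, 3, 3 and 3 fell and 3, 3 and 1 rose. The water channel Aqp1 fell in Cx43 heterozygous (-1.78 ± 0.21) and Cx32 null brain (-1.36 ± 0.21). The homeobox gene Otx2 rose by 1.71 ± 0.23 in Cx43 heterozygous brain. Red blood cell genes fell in 1, 6 and 4 of 16 cases and rose in 2, 3 and 2 (list adjusted p = 0.69, 0.741 and 0.287). With p adjusted over the list alone, 5, 6 and 5 fell and 2, 4 and 2 rose. The haem synthesis gene Alas2 fell (-1.63 ± 0.30) in Cx43 heterozygous brain. Skin genes fell in 2, 5 and 5 of 10 cases and rose in 0, 0 and 1 (list adjusted p = 0.245, 0.306 and 0.293). The numbers were 4, 5 and 5 lower and 0, 1 and 1 higher adjusted over the list alone. Skeletal muscle genes fell in 2 and 5 of 14 cases in Cx43 null and Cx43 heterozygous brain and rose in 0 and 1, counts that were alike when adjusted over the list alone (list adjusted p = 0.245 and 0.395). Of 18 genes of the reference tissues 1, 5 and 5 fell and 1, 1 and 1 rose (list adjusted p = 0.298, 0.395 and 0.136). When adjusted over the list alone, 1, 6 and 5 fell and 1, 1 and 1 rose.

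No list of neuronal signalling genes passed in any of the 3 lines. The vesicular GABA transporter Slc32a1 rose by 1.12 ± 0.19, 0.98 ± 0.19 and 0.88 ± 0.19 in Cx43 null, Cx43 heterozygous and Cx32 null brain, and the interneuron calcium buffer Calb1 by 0.81 ± 0.16, 0.57 ± 0.16 and 0.67 ± 0.16. In the GABA list of 9 genes 2, 2 and 2 rose and 0, 1 and 1 fell (list adjusted p = 0.422, 0.817 and 0.8). Adjusted over the list alone, 2, 2 and 2 rose and 1, 1 and 1 fell. In the synaptic vesicle list of 12 genes 1, 2 and 1 rose and 1, 5 and 5 fell (list adjusted p = 0.575, 0.491 and 0.639). With p adjusted over the list alone, 2, 3 and 2 rose and 4, 5 and 5 fell. Bsn, the active zone protein bassoon, rose by 0.70 ± 0.19, 0.82 ± 0.19 and 0.62 ± 0.19, and the vesicle glycoprotein Sv2a fell in Cx43 heterozygous (-1.70 ± 0.37) and Cx32 null brain (-1.51 ± 0.37). Of 8 glutamate signalling genes 0, 1 and 2 rose and 0, 1 and 1 fell (list adjusted p = 0.575, 0.586 and 0.711). The numbers were 0, 1 and 2 higher and 0, 2 and 4 lower adjusted over the list alone. The NMDA receptor subunit Grin2d rose in Cx43 heterozygous (0.67 ± 0.23) and Cx32 null brain (0.96 ± 0.25). Of 13 channel genes 1, 3 and 4 rose and 0, 4 and 1 fell (list adjusted p = 0.967, 0.965 and 0.8). When adjusted over the list alone, 1, 5 and 4 rose and 0, 5 and 1 fell. The calcium channel subunit Cacnb2 rose in all 3 lines (0.81 ± 0.23, 0.93 ± 0.21 and 0.81 ± 0.21). Of 17 calcium and purine signalling genes 0, 1 and 3 rose and 1, 4 and 4 fell (list adjusted p = 0.97, 0.62 and 0.781). Adjusted over the list alone, 0, 1 and 5 rose and 1, 4 and 6 fell. The purine receptor P2rx4 fell (-1.20 ± 0.38) in Cx43 heterozygous brain.

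Junction and growth lists did not pass as a whole either. Ctnnb1, which encodes beta-catenin of adherens junctions and Wnt signalling, fell in Cx43 null (-1.41 ± 0.32), Cx43 heterozygous (-2.13 ± 0.32) and Cx32 null brain (-1.91 ± 0.32). In the junction list of 24 genes 0, 2 and 1 rose and 3, 6 and 8 fell (list adjusted p = 0.402, 0.352 and 0.287). Counts were alike when adjusted over the list alone. In the Wnt and Notch list of 22 genes 0, 2 and 2 rose and 2, 3 and 1 fell (list adjusted p = 0.967, 0.834 and 0.781). With p adjusted over the list alone, 0, 2 and 1 rose and 2, 3 and 1 fell. Of 33 tubulin and motor genes 1, 3 and 6 rose and 2, 6 and 4 fell (list adjusted p = 0.733, 0.62 and 0.8). The numbers were 1, 3 and 7 higher and 1, 6 and 5 lower adjusted over the list alone. The kinesin Kif3b fell in all 3 lines (-1.41 ± 0.30, -1.27 ± 0.30 and -1.30 ± 0.30). Cell cycle genes rose in 2, 5 and 5 of 47 cases and fell in 1, 8 and 4 (list adjusted p = 0.809, 0.992 and 0.582). When adjusted over the list alone, 0, 5 and 5 rose and 0, 8 and 2 fell. The cyclin Ccne1 rose in all 3 lines (0.76 ± 0.22, 0.74 ± 0.22 and 0.89 ± 0.22). Apoptosis genes rose in 2, 3 and 3 of 22 cases and fell in 3, 5 and 3 (list adjusted p = 0.97, 0.852 and 0.835). Adjusted over the list alone, 3, 3 and 4 rose and 3, 6 and 3 fell. The pro-apoptotic Bid rose in all 3 lines (1.00 ± 0.19, 0.94 ± 0.19 and 1.17 ± 0.19). Cholesterol synthesis genes rose in 1, 1 and 1 of 11 cases and fell in 1, 4 and 1 (list adjusted p = 0.69, 0.128 and 0.8). With p adjusted over the list alone, 1, 1 and 1 rose and 2, 5 and 1 fell. The squalene synthase Fdft1 fell in all 3 lines (-1.47 ± 0.43, -2.53 ± 0.43 and -1.83 ± 0.43). In Cx43 null brain 5 of 57 ribosomal protein genes fell and 0 rose (4 and 0 adjusted over the list alone; list adjusted p = 0.0725), and 1 of 21 glycolysis genes fell and 1 rose (1 and 1; 0.245). Median, mean and test differed in sign for neurons, Wnt and Notch, apoptosis and calcium signalling in Cx43 null brain, for cell cycle in Cx43 heterozygous brain, and for neurons, choroid plexus, tubulins, channels and apoptosis in Cx32 null brain.

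The 3 lines shared many calls against wild type. Cx43 heterozygous and Cx32 null brain had 1170 higher and 1648 lower transcripts in common and 7 in opposite directions. Cx43 null brain shared 1328 calls with Cx43 heterozygous (474 higher, 854 lower, 2 opposite) and 1343 with Cx32 null brain (513 higher, 830 lower, 1 opposite). All 3 lines had 432 higher and 794 lower transcripts in common, with Gja1, Igfbp4, Ctnnb1 and Ndufv1 among the lower and Slc32a1, Calb1, Bsn and Bid among the higher. Unrelated calls of these sizes would give 624.5, 249.8 and 217.5 shared transcripts. The lines share their controls, and transcripts are not independent replicates. Unchanged groups simulated with shared controls had a mean correlation of 0.50 across transcripts and 0 shared calls, while the lines had correlations of 0.85, 0.83 and 0.86. The simulation gave every group the same spread, whereas the real median SD was 0.38 in wild type and 0.20 to 0.27 in the lines. It therefore cannot show how much correlation the shared controls alone would give. With each line set against its own 2 wild-type arrays, the median shared count over 6 ways was 872 (602 to 1240) for Cx43 heterozygous with Cx32 null, 409 (15 to 586) for Cx43 null with Cx43 heterozygous and 329 (15 to 449) for Cx43 null with Cx32 null. The median correlations in these fits were 0.60, 0.55 and 0.55 in the same order. The shared counts of Cx43 null brain with the heterozygous and the Cx32 null line were 732 and 727 without wild-type replicate 1, 453 and 445 without wild-type replicate 2, 2574 and 2589 without wild-type replicate 4, 2073 and 2103 without Cx43 null replicate 1, 466 and 464 without replicate 2, 101 and 103 without replicate 3 and 524 and 522 without replicate 4.

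Cx43 null and Cx43 heterozygous brain differ by their labels in the dose of Gja1, but Gja1 itself did not pass between them. On Cx43 null replicate 1 it lay at -0.60, above all 4 heterozygous arrays (-1.86 to -1.09). Nav3, which encodes a neuronal microtubule-associated protein, was 4.98-fold higher in Cx43 null brain (2.32 ± 0.27, adjusted p = 0.000378), and the endothelin receptor Ednrb 4.13-fold higher (2.05 ± 0.24, adjusted p = 0.000527). Syn1 was 3.18-fold higher (1.67 ± 0.27, adjusted p = 0.00567), and the glucose transporter Slc2a1, in a block out of step on some arrays, was higher by 0.94. The apelin receptor Aplnr was 3.45-fold lower (-1.79 ± 0.22, adjusted p = 0.00056), the mucin Muc1 4.05-fold lower (-2.02 ± 0.24, n = 4 and 3, adjusted p = 0.000939), and Panx1 was lower (-1.76 ± 0.33, adjusted p = 0.0128). In all, 208 transcripts passed, 110 higher and 98 lower in Cx43 null brain.

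Ubl4b was 4.87-fold lower in Cx43 null than in heterozygous brain (-2.28 ± 0.44), Sqor, which oxidises sulfide in mitochondria, 3.91-fold lower (-1.97 ± 0.34) and Ctss 3.83-fold lower (-1.94 ± 0.47, adjusted p = 0.0498). Sfxn3, a mitochondrial amino acid carrier (1.83 ± 0.40, n = 4 and 3), and 1600014C10Rik (1.75 ± 0.39) were higher. Of the 21 glycolysis genes 1, Slc2a1, was higher and 0 lower (1 and 0 adjusted over the list alone; median 0.42, camera adjusted p = 0.00599; adjusted p = 0.981 with an estimated correlation), and without Cx43 null replicate 1 the list had a median of 0.25 and an adjusted p of 0.226 (lowest 0.000294 over its alternatives). The other 26 lists did not pass (adjusted p = 0.0502 to 0.973), and for endothelium, skeletal muscle, meninges and channels median, mean and test differed in sign. The gene count was 91, 95, 105 and 98 without heterozygous replicates 1 to 4, and 85, 82, 107 and 223 without null replicates 1 to 4. The calls of Sfxn3, 1600014C10Rik, Ubl4b and Ctss were each lost without 1 of several arrays (highest adjusted p = 0.119, 0.0839, 0.06 and 0.15). With the values as deposited, the median of all transcripts shifted by -0.17 and the share of passing transcripts that were higher went from 52.9% to 21.3%.

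By their labels, Cx43 null and Cx32 null brain lack connexins of different glial cells. Gjb1 could not be followed, and Gja1 fell against wild type in both lines. Hddc3 was 3.24-fold lower in Cx43 null brain (-1.70 ± 0.21, adjusted p = 0.00313). Pglyrp1, a peptidoglycan recognition protein of innate immunity, was 2.67-fold higher (1.42 ± 0.25, adjusted p = 0.0326), Tor3a, a torsin ATPase, 2.04-fold higher (1.03 ± 0.18, n = 4 and 3, adjusted p = 0.0406) and the epithelial junction protein Evpl 1.91-fold higher (0.94 ± 0.17, adjusted p = 0.0406). These are the 4 named genes among 12 transcripts that passed, 10 higher and 2 lower. The calls of Pglyrp1, Tor3a and Evpl were each lost without 1 of several arrays (highest adjusted p = 0.153, 0.189 and 0.153), and that of Hddc3 was not. As a list, glycolysis was higher in Cx43 null brain (median 0.31, adjusted p = 0.00033, 0 of 21 genes past the threshold, 1 higher and 0 lower adjusted over the list alone), as was skeletal muscle (median 0.31, adjusted p = 0.0377, 0 of 14, and 0 adjusted over the list alone), and cell cycle was lower (median -0.12, adjusted p = 0.0377, 0 of 47, and 1 higher and 0 lower adjusted over the list alone). With an estimated correlation all 3 had an adjusted p = 0.884. The muscle and cell cycle calls were each lost in 6 of 14 alternatives (highest adjusted p = 0.395 without Cx32 null replicate 4 and 0.476 without Cx43 null replicate 3). The glycolysis median was 0.13 without Cx43 null replicate 1 and 0.47 without replicate 4, and the cell cycle median was -0.04 without replicate 3. The other 24 lists did not pass (adjusted p = 0.112 to 0.995), with signs that differed between median, mean and test for neurons, channels, cholesterol synthesis, apoptosis, glutamate signalling and skin. The gene count was 3, 8 and 5 without Cx32 null replicates 2, 3 and 4, 4, 4 and 3 without Cx43 null replicates 1, 2 and 3, and 39 without Cx43 null replicate 4, while at an unadjusted p under 0.05 it was 1317.

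Cx43 heterozygous and Cx32 null brain differed in Ctss, which was 7.08-fold higher in the heterozygous line (2.82 ± 0.51, n = 4 and 3, adjusted p = 0.0091), in Ubl4b, 6.90-fold higher (2.79 ± 0.44, adjusted p = 0.00345), and in Muc1, 5.12-fold higher (2.36 ± 0.26, n = 3 in each group, adjusted p = 0.000308). Nav3 was 5.59-fold lower (-2.48 ± 0.27, adjusted p = 2e-04), Ednrb 4.28-fold lower (-2.10 ± 0.24) and the vasohibin Vash2 4.15-fold lower (-2.06 ± 0.23). Meioc, a factor of meiosis (2.16 ± 0.28, n = 4 and 3), and Fbxl18 (1.93 ± 0.33, n = 3 in each group) were higher, and Hddc3 (-1.86 ± 0.21) and the lipocalin Lcn2 (-1.57 ± 0.26) were lower. In all, 183 transcripts passed, 134 higher and 49 lower in Cx43 heterozygous brain. Cholesterol synthesis was lower as a list (median -0.46, adjusted p = 0.044, 0 of 11 genes past the threshold and 0 adjusted over the list alone), with an adjusted p = 0.954 with an estimated correlation. The call was lost without Cx32 null replicate 1, 2 or 4 or heterozygous replicate 1 or 2 (highest adjusted p = 0.127, lowest over its alternatives 0.0166). The other 26 lists did not pass (adjusted p = 0.182 to 0.992), with such differences in sign for endothelium, red blood cells, astrocytes, microglia and glycolysis. The gene count was 75 without Cx32 null replicate 2, 108 and 111 without heterozygous replicates 1 and 2, and Ctss was lost without Cx32 null replicate 4 (adjusted p = 0.052).

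The arrays of the groups lay apart to different degrees. The median SD over transcripts was 0.38 ± 0.12 (jackknife SE, n = 4) among wild-type arrays, 0.27 ± 0.05 among Cx43 null, 0.21 ± 0.02 among Cx32 null and 0.20 ± 0.02 among Cx43 heterozygous arrays. Without wild-type replicate 1 the wild-type value was 0.25. Each array was also placed on the axis from the mean of Cx43 heterozygous and Cx32 null brain, at 0, to the wild-type mean, at 1. An array was left out of the mean of its own group, so positions in a group need not average 0 or 1, and Cx43 null arrays enter no mean. For replicates 1 to 4, the wild-type arrays lay at 1.15, 0.88, 0.70 and 0.52 and the Cx43 null arrays at 0.63, 0.29, 0.06 and 0.17. Wild-type replicate 4 thus lay further from the wild-type mean than Cx43 null replicate 1 did.

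**Figure D3:**
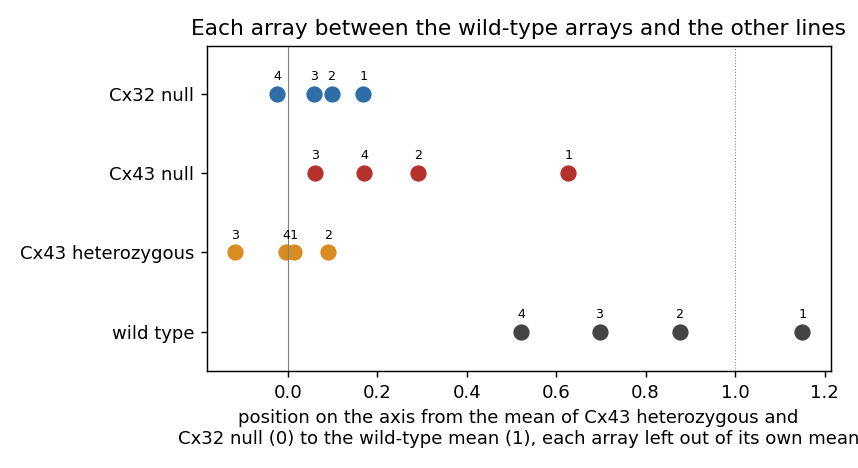
Position of each of the 16 arrays on the axis from the mean of Cx43 heterozygous and Cx32 null brain (0) to the wild-type mean (1), with 1 point per array and each array left out of the mean of its own group. The wild-type arrays lie between 0.52 and 1.15, and Cx43 null replicate 1 lies at 0.63.

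**Figure D4:**
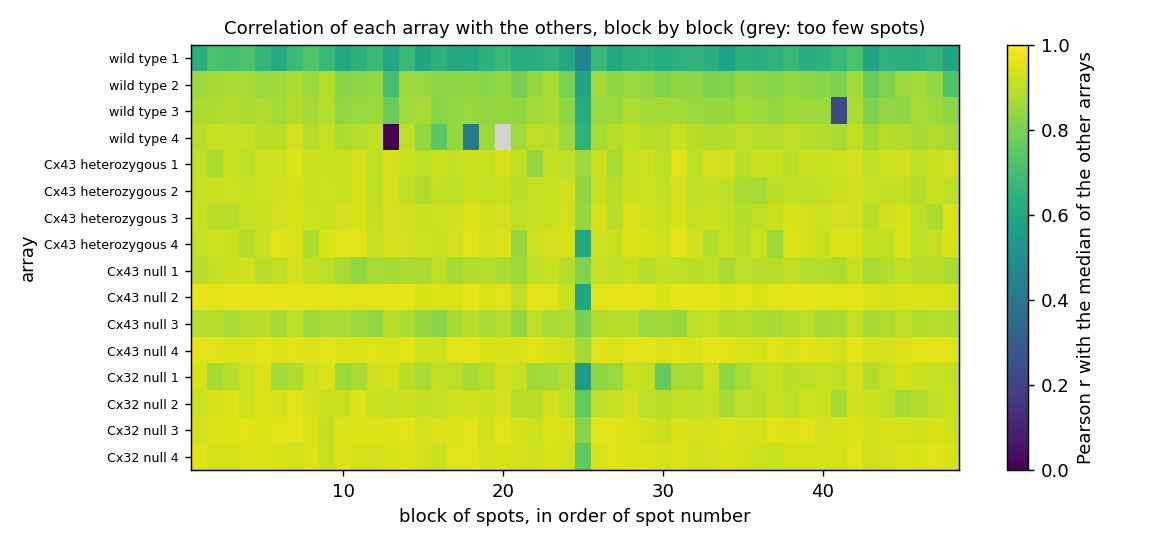
Correlation of each array with the median of the other arrays in each of the 48 blocks of spots, with arrays down the side and blocks along the bottom. In 7 of 768 array and block pairs, in 5 blocks, an array fell well below its usual correlation or had too few spots. This counts 3 of the arrays of the block in which 7 arrays were displaced against the other 9.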

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

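The 6 tests of the 3 patterns weighed below were chosen only after the results they measure were seen, while the counts over other splits of the arrays were planned.

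Single arrays stood apart from the other 3 of their group for 14 values of named genes. Wild-type replicate 1 stood apart for Gstp1 (2.07, mean of the others 0.92), C030034L19Rik (-1.39, others -0.44), Plg (-2.88, others -1.34) and Add2 (-0.77, others 0.09), and wild-type replicate 4 for Gstm6 (-0.61, others 1.23). Cx32 null replicate 1 stood apart for Lrrc40 (0.65, others -1.05) and Gstp1 (0.27, others -1.23), and replicate 4 for 1600014C10Rik (-0.71, others -1.59). Cx43 heterozygous arrays stood apart for Stard10 (replicate 2, -3.08, others -3.72), Ednrb (replicate 4, 0.54, others -0.70), Ctss (replicate 3, 0.52, others -1.35) and Meioc (replicate 4, -0.31, others -0.44). Cx43 null arrays did for Ccdc184 (replicate 4, 2.74, others 1.91) and Syn1 (replicate 1, 1.41, others 0.90). Among list medians, the proteasome median stood apart on wild-type replicate 1 (1.47, others 0.56), the ribosomal median on Cx43 null replicate 1 (0.21, others 0.04) and the reference tissue median on Cx43 null replicate 4 (-5.40, others -4.56). Of 241 groups of 4 values tested, 17 had an array apart, and chance marks about 1 in 20. Gstp1, Lrrc40 and Stard10 lie in blocks of spots out of step on some arrays. In the block of Gstp1 and Lrrc40, the spots of Cx32 null replicate 1 matched those of replicates 2 to 4 best 1 row apart. Its 2 values apart were therefore read from other spots than theirs.

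The effects of the lines against wild type differed from each other for some genes, by a test of the difference itself. Ubl4b differed by -2.28, Nexmif by -1.55, Myo16 by -1.33 and Gm12966 by 1.21 between Cx43 null and Cx43 heterozygous brain. Hddc3 differed by -1.70 between Cx43 null and Cx32 null brain, and Ubl4b by 2.79 and Hddc3 by -1.86 between Cx43 heterozygous and Cx32 null brain. In all, 208, 12 and 183 transcripts differed between these pairs of lines.

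In Cx43 heterozygous and Cx32 null brain the wild-type arrays stood apart from the lines for many genes, with falls shared by Igfbp4, Ctnnb1 and Ndufv1. Wild-type replicate 1 alone is argued against, since 4020 transcripts passed in Cx43 heterozygous brain without it. RNA of non-brain tissue in the wild-type samples is argued against as the whole cause, while a part stays open. Among 1530 genes with brain above the reference in the lines, 275 passed as higher in wild type than in Cx43 heterozygous brain. Of all 14292 transcripts 2519 did, so the count is not particular to these genes. Of 167 genes chosen for low values in the lines, which by itself favours wild type, 158 were higher there (median 0.917). The liver gene Alb differed by 0.102 ± 0.241, but 1 gene cannot decide the point. Hpx and plasminogen, Plg, both named for the size of their change, were at -3.35 and -3.09 in Cx43 heterozygous brain. In the reference tissue list 5 of 18 genes fell and 1 rose in that line (camera, adjusted p = 0.395). A technical difference of the wild-type arrays and a shared biological effect of losing a connexin cannot be told apart, since both would follow the genotype groups. The same holds for any other difference between the wild-type samples and the lines. Not every array followed its group. On the axis from the other lines to wild type, wild-type replicate 4 lay at 0.522 and Cx43 null replicate 1 at 0.627. The mean correlation of Cx43 null replicate 1 with its own group (0.862) was above that with the 4 wild-type arrays. It was below that with wild-type replicates 2 to 4 (0.894).

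Of the genes named by size in Cx43 null brain, 9 of 19 lay in a few blocks of spot numbers, among them Gmppb, Kif1a, Tfpt and Stard10, against 4 of 19 in Cx43 heterozygous brain, 2 of 20 in Cx32 null brain and 0 between the lines. Of all calls in Cx43 null brain 212 of 1556 lay there, and of all transcripts tested 1677 of 14292. A shift of the spot grid by 1 row on some arrays is a candidate explanation for part of the 9. Shifts of a single array occurred in blocks that hold few of these genes. In 1 block of wild-type replicate 3, which holds none of the 9, the correlation with the other arrays rose from 0.224 to 0.854 when its spots were moved by 1 row. In 1 block of wild-type replicate 4, which holds 1 of the 4 spots of Wsb1, it rose from 0.403 to 0.886. For the 9 themselves the explanation rests on the block of Tfpt, Cnnm4, Lrrc40 and Gstp1, which also holds a spot of Wsb1. There, all 63 pairs between the 7 displaced and the 9 other arrays matched best 1 row apart. All 4 wild-type arrays were among the 7, and the other 9 were arrays of the lines. The changes of Tfpt, Cnnm4, Lrrc40 and Gstp1 against wild type therefore mostly compare different spots. The block of Gmppb, Ankrd50, Kif1a and Stard10 on wild-type replicate 4 (correlation 0.002) stays open, and no biological explanation was tested. Without that array Gmppb, Ankrd50 and Stard10 still passed in Cx43 null brain, so their calls did not rest on it, while Kif1a did not pass.

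Cx43 null replicate 1 lay nearer to the wild-type arrays on the axis than the other Cx43 null arrays did. A wild-type sample under the wrong label is argued against: Gja1 on it was -0.604, while the lowest wild-type array was at 1.13. The blocks out of step are argued against, since without them its mean correlation with wild-type replicates 2 to 4 was 0.91. A technical difference shared with the wild-type arrays, and variation between animals, may both contribute and stay open. Without this array 2530 transcripts passed against wild type. Wild-type replicate 4 stood apart in the other direction, at 0.522 on the axis against 0.627 for Cx43 null replicate 1. Its mean correlation was 0.848 with the Cx43 null arrays and 0.808 with the other wild-type arrays, among them replicate 1 at 0.691.

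Counts over all 35 splits of the 8 arrays of a comparison into 4 and 4 were set beside the real split. Only the real split gave a count as large for the genes of Cx43 heterozygous (4481, highest other split 1) and Cx32 null brain (3962, highest other 24) against wild type. The same held between the lines for 208 (highest other 0), 12 (highest other 4) and 183 (highest other 1). Chance is argued against in these comparisons but not excluded, because 1 of 35 is the smallest share that the splits can give. Splits that mix 2 groups that differ also widen the spread within a group, which lowers their counts. The count of Cx43 null against wild type did not stand alone, so chance is not excluded there. In all, 2 splits gave a count as large as 1556. The split that put wild-type replicates 1 to 3 with Cx43 null replicate 1 gave 2182. That split exchanges wild-type replicate 4 and Cx43 null replicate 1. Chance is not excluded for the counts of gene lists either. In the order of the report, 23, 12, 10, 30, 27 and 23 of the 35 splits gave as many lists as the real 4, 6, 7, 1, 3 and 1, and the highest other splits gave 8, 9, 12, 11, 10 and 9.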

How the results depend on the processing

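Of the alternatives below, leaving out the blocks out of step and leaving out wild-type replicate 1 with Cx43 null replicate 1 were chosen only after the data were seen. No named gene and no test of a called list changed direction, but the ribosomal median in Cx32 null brain turned from -0.25 to 0.10 without wild-type replicate 1. With values as deposited the share of passing transcripts that were higher went from 43.8% to 62.8% in Cx43 heterozygous and from 47.8% to 57.2% in Cx32 null brain against wild type, and from 52.9% to 21.3% between Cx43 null and Cx43 heterozygous brain. Gja1 fell against wild type in every alternative, and in Cx43 null brain it was -3.40 with the 2 groups fitted alone, no longer past the threshold (adjusted p = 0.0747, range 5.17e-06 to 0.0747). For named genes, 905 values stayed on their side of the threshold, 52 no longer passed and 13 passed where they had not, over the settings other than 1 array left out. With 1 array left out these numbers were 613, 66 and 1. They include Gja1 between the lines, which did not pass to begin with. Causes were not tested unless given.

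Transcript counts of Cx43 null against wild type (1556) were 0 by limma with the 2 groups alone (3111 at an unadjusted p under 0.05), 4008 with array weights, 2342 with each probe on its own, 2944 by a fold of at least 1.5 and unadjusted p, and 822 with wild-type replicates 2 and 3 as 1 sample. Cx32 null against wild type (3962) gave 2323 with the groups alone. Cx43 null against Cx43 heterozygous (208) gave 80 with values on all 16 arrays, where fewer transcripts are tested, 1919 with array weights and 1207 by fold. Cx43 null against Cx32 null (12) gave 47 under quantile scaling, 22 under cyclic loess, 5 with values on all 16 arrays, 22 with at least 2 of 4 values, 7 with the groups alone, 6 with a replicate block, 618 with array weights, 23 with each probe on its own and 755 by fold. Cx43 heterozygous against Cx32 null (183) gave 82 with values on all 16 arrays, 283 with at least 2 of 4 values, 281 with the groups alone, 926 with array weights, 1018 by fold and 335 without wild-type replicate 1 and Cx43 null replicate 1. The labels do not pair the replicate numbers. After the mean of each group was subtracted, pairs of arrays from different groups had a median correlation of 0.0184 if their numbers matched. Pairs with other numbers had 0.00113.

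Calls shared by Cx43 null with Cx43 heterozygous and Cx32 null brain (1328 and 1343) were 2289 and 2339 by fold, 732 and 741 with wild-type replicates 2 and 3 as 1 sample, and 409 and 329 with each line given its own 2 wild-type arrays, which gave 872 for Cx43 heterozygous with Cx32 null.

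Lists called between Cx43 null and Cx43 heterozygous (1) were 3 with values as deposited, 3 under quantile scaling, 3 with a replicate block, 3 without the blocks out of step and 0 without wild-type replicate 1 and Cx43 null replicate 1. Cx43 null against Cx32 null (3) gave 1 under quantile scaling, and Cx43 heterozygous against Cx32 null (1) gave 2 under quantile scaling and 2 with values on all 16 arrays. With an estimated correlation in camera the 6 comparisons gave 0, 0, 0, 0, 0 and 0 lists, and 0 at an unadjusted p under 0.05.

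With 1 array left out, transcript counts ranged from 107 to 3052 for Cx43 null against wild type (without Cx43 null replicate 3 and wild-type replicate 4), 82 to 223 against Cx43 heterozygous (without Cx43 null replicates 2 and 4), 3 to 39 against Cx32 null (lowest without Cx32 null replicate 2 or Cx43 null replicate 3, highest without Cx43 null replicate 4) and 75 to 189 for Cx43 heterozygous against Cx32 null (without Cx32 null replicates 2 and 3). Shared calls ranged from 101 to 2574 and from 103 to 2589. Lists called ranged from 2 to 5 for Cx43 null against wild type, 0 to 5 against Cx43 heterozygous, 1 to 4 against Cx32 null and 0 to 2 for Cx43 heterozygous against Cx32 null. The median SD ranged from 0.247 to 0.427 in wild type, 0.185 to 0.212 in Cx32 null, 0.174 to 0.198 in Cx43 heterozygous and 0.208 to 0.293 in Cx43 null. Signal over background cannot be given, since the deposited table holds ratios alone.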

Other observations

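The intervals around the medians of genes next to Gja1 and Gjb1, and Xist and Eif2s3y as genes to look at, were chosen only after the results were seen.

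Panx1, which encodes pannexin 1, rose 3.49-fold in Cx43 heterozygous brain (1.80 ± 0.33 SE, adjusted p = 0.00114) and did not pass in Cx43 null (0.05, adjusted p = 0.937) or Cx32 null brain (0.52, adjusted p = 0.245). The difference between Cx43 null and Cx43 heterozygous brain passed (-1.76, adjusted p = 0.0128), and that between Cx43 heterozygous and Cx32 null did not (1.28, adjusted p = 0.0686). Gjb5, a connexin of skin and placenta, did not pass in Cx43 null (0.31, adjusted p = 0.345), Cx43 heterozygous (0.20, adjusted p = 0.534) or Cx32 null brain (0.46, adjusted p = 0.153). With Gja1 these are the 3 connexin and pannexin genes measured, too few for a list test.

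Oligodendrocytes, the cells of connexin 32, had 4 measured genes, also too few for a list test. Mbp, the myelin basic protein gene, fell 1.79-fold in Cx43 heterozygous brain (-0.84 ± 0.25 SE, adjusted p = 0.0187) and 1.65-fold in Cx32 null brain (-0.73 ± 0.25, adjusted p = 0.041), and was at -0.51 in Cx43 null brain (adjusted p = 0.174). The neuregulin receptor gene Erbb3 fell 1.71-fold in Cx43 heterozygous brain (-0.78 ± 0.24, adjusted p = 0.0219) and did not pass in Cx43 null (adjusted p = 0.437) or Cx32 null brain (adjusted p = 0.123). Tspan2 (adjusted p = 0.364, 0.297 and 0.428) and Pdgfra, the receptor of oligodendrocyte precursors (0.592, 0.382 and 0.65), passed in none of Cx43 null, Cx43 heterozygous and Cx32 null brain. The sex-linked genes Xist (0.622, 0.963 and 0.881) and Eif2s3y (0.878, 0.888 and 0.921) did not pass either.

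Genes next to a disrupted gene can carry alleles of the strain in which it was made. The 40 measured genes nearest Gja1 had a median absolute t of 0.939 between Cx43 null and Cx32 null brain, at percentile 90.7 of 10000 random sets of 40, and the 40 nearest Gjb1 had 0.719, at percentile 39.4. Neither passed the 95th percentile of the random sets (0.991 and 0.983). The bootstrap intervals of the 2 medians (0.706 to 1.18 and 0.564 to 1.04) reach above it, so passenger alleles stay open at both genes.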
